A study of Mus musculus with 6 samples.

How the data were processed

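RNA of whole mouse retina, collected at postnatal day 17, was measured by sequencing in 6 libraries. Per the labels, 3 Control libraries came from C57BL/6J pups kept in room air, and 3 libraries came from pups with oxygen-induced retinopathy (OIR). The OIR pups were exposed to 75% oxygen from postnatal day 7 to day 12 and were then returned to room air. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may in part be technical. The library protocol in the labels describes material of another species, so library type, selection and strand are treated as uncertain.

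The deposited files hold 1 RPKM-type value per gene symbol and library, a read number divided by gene length and by library size. Whether reads or fragments were counted, and the genome build, annotation and counting program, are not given in the sources used here. Bowtie2 2.0.6 and TopHat2 2.0.12 are named, per the submitters' processing notes. Without a stated build no genome coordinates are given. Genes are named by the symbols in the files. Without knowledge of strand or of the treatment of shared reads, values of near-identical genes, such as the haemoglobin genes Hba-a1 and Hba-a2 and the gamma crystallins, are uncertain for each single gene.

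Depth was recovered from the values. Low genes take steps that are whole multiples of 1 read, which gave the relative depth of the libraries. The lengths of GENCODE M21 transcripts, used for lengths only, gave the absolute depth through 124 genes. For each gene the smallest whole length was then taken that made its 6 values whole numbers of reads within 0.02 of a read. Of the 17953 genes with a value above 0 in any library, 99.9% came out whole, as did 12111 of the 12112 tested genes. The libraries held 35615501 to 38025623 reads, a ratio of 1.07 between the highest and the lowest.

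The files list 22173 genes, and 4220 were at 0 in all 6 libraries. Genes with a value of at least 1 in at least 3 libraries were tested, and the other 10061 genes were not. The values are not counts, so the count tests planned for count tables, edgeR and DESeq2, were not used. The test stated beforehand for normalized values was used in their place. It was limma 3.58.1 in R 4.3.3, with trend and robust options, on log2(value + 1), with group as the only term and 4 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Each adjusted p of a gene in the report is from this limma fit, or from a limma fit under the alternative named beside it. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Ratios are of the plain group means.

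Before the data were examined, 34 gene lists were written from textbook markers. The 30 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. Lists were also tested with camera at an estimated correlation and with fry. Y-linked genes served as a check and were not tested as a list, and Xist was not analysed here. The genes named in the text follow a rule that was also fixed before the data were examined. It takes Bgn, Cxcl12, Cxcr4, Ackr3 and Vegfa in every case. It then takes the 10 largest positive and the 10 largest negative log2 fold changes among genes past the threshold whose groups do not overlap and whose mean is at least 2 CPM (reads scaled to library size). Gene models named Gm with digits, names ending in Rik, names with -ps and digits, names starting with AC, AL or BC with digits, genes with no symbol (taken as names starting with LOC) and sex-linked genes were passed over. From each list the rule takes up to 4 tested members with the smallest adjusted p, or up to 2 where no member passed. It covers 128 genes. Genes outside the rule are named as such, and some genes that the rule takes are not reported here.

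The gene test was tested on simulated data for the comparison of OIR with Control, with 12015 genes in the step. It recovered 6.06% of the 66 genes changed 1.25-fold, 47.8% of the 67 changed 1.5-fold and 83.1% of the 65 changed 2-fold. It called 2 of 11817 unchanged genes, 2.17% of its calls. No list passed in the simulation of 30 lists. Simulated genes were drawn independently of each other, so the list test was not tried at the correlations between genes in the data. Those were estimated at 0.00266 for the barrier list to 0.993 for the lens list.

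Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, a pseudocount of 0.1, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, and an absolute log2 fold change of at least 1. Alternatives added after seeing the data were limma-voom on the recovered reads, the lens gene level as a covariate, both lens-rich libraries left out, and lens reads removed from the total. A pseudocount of 0.1 with Control 1 left out was also added then and is reported for Bgn only. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.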

Results

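Gene expression was measured in whole retina of mouse pups at postnatal day 17, in 3 Control libraries from room air and 3 libraries from oxygen-induced retinopathy. In this model, oxygen exposure of the pups stops and reverses the growth of retinal vessels, and after the return to room air the poorly perfused retina becomes hypoxic and grows abnormal vessels. The recovered depth was 37199172 reads in Control 1, 37082910 in Control 2 and 35615501 in Control 3. The OIR libraries held 36957706 reads in OIR 1, 36617655 in OIR 2 and 38025623 in OIR 3. Genes of the eye lens took 6.86% of the reads in Control 3 and 0.592% in OIR 2. Their share was 0.0237% in Control 1, 0.0677% in Control 2, 0.0508% in OIR 1 and 0.0217% in OIR 3.

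**Figure D1:**
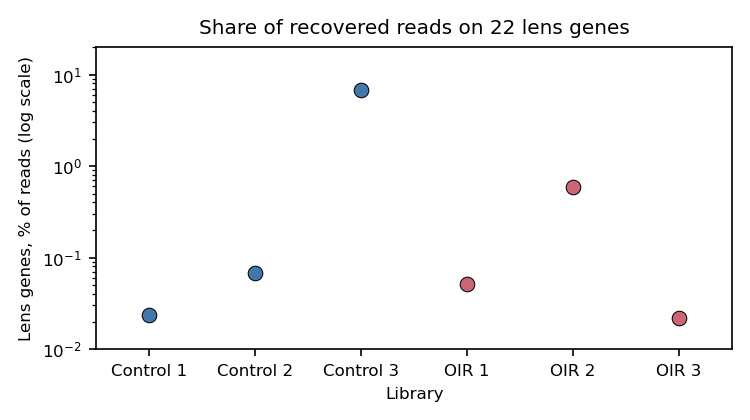
Share of the recovered reads that fell on 22 lens genes, in percent on a log scale, with 1 point per library, blue for Control and red for OIR. Control 3 stands at 6.86% and OIR 2 at 0.592%, and the other 4 libraries lie between 0.0217% and 0.0677%.

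The series names biglycan and the chemokine CXCL12 in pericytes and asks which genes change in the retina during pathological vessel growth. Whole retina was sequenced, so the values describe RNA of the tissue and do not show the level in pericytes. Bgn, which encodes the matrix proteoglycan biglycan, was at 5.06 ± 2.33 RPKM in Control and 17.97 ± 3.16 RPKM in OIR (SD, n = 3 each), a ratio of 3.55. Cxcl12 was at 2.65 ± 0.363 RPKM in Control and 2.75 ± 0.329 RPKM in OIR, a difference below the spread between libraries. Cxcr4, the receptor through which CXCL12 guides migrating cells, rose from 0.994 ± 0.140 to 3.01 ± 0.461 RPKM. Ackr3, the gene of the scavenging CXCL12 receptor, was at 1.63 ± 0.346 RPKM in Control and 1.64 ± 0.573 RPKM in OIR. Vegfa, which encodes the main growth factor of endothelial cells, rose from 45.6 ± 1.09 to 128.6 ± 20.96 RPKM.

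The log2 fold change of Bgn was 1.72 with a standard error of 0.386 and an adjusted p of 0.0476, and its 3 OIR values all lay above its 3 Control values. Its Control values were 2.37 RPKM in Control 1, 6.43 in Control 2 and 6.39 in Control 3. For Cxcl12 the log2 fold change was 0.04, with a standard error of 0.102, an adjusted p of 0.815 and a 95% interval from -0.19 to 0.26. Between 570 and 824 reads per library lay behind the Cxcl12 values. Cxcr4 rose by a ratio of 3.03, with an adjusted p of 0.000306. The interval of Ackr3 ran from -0.35 to 0.34, with an adjusted p of 0.983. As a list, these 4 genes did not pass, with a camera adjusted p of 0.0582, an adjusted p of 0.293 with an estimated correlation, and 2 members higher both over all genes tested and adjusted over the list alone. Since the series names these genes, the list is not independent evidence of their direction, and it passed without Control 1, Control 2 or OIR 2, at 0.0418, 0.0486 and 0.0453. The call of Bgn ended when Control 2, OIR 1, OIR 2 or OIR 3 was left out, with adjusted p of 0.0896, 0.174, 0.0864 and 0.176 and log2 fold changes of 1.91, 1.68, 1.86 and 1.62. It also ended with a pseudocount of 0.1, at an adjusted p of 0.0604, and with the lens gene level as a covariate or without both lens-rich libraries, at 0.0576 and 0.102. Without Control 1 the call of Bgn held, at a log2 fold change of 1.34. With a pseudocount of 0.1 and Control 1 left out, a fit chosen after the values of Bgn were seen, its adjusted p was 0.000883.

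**Figure D2:**
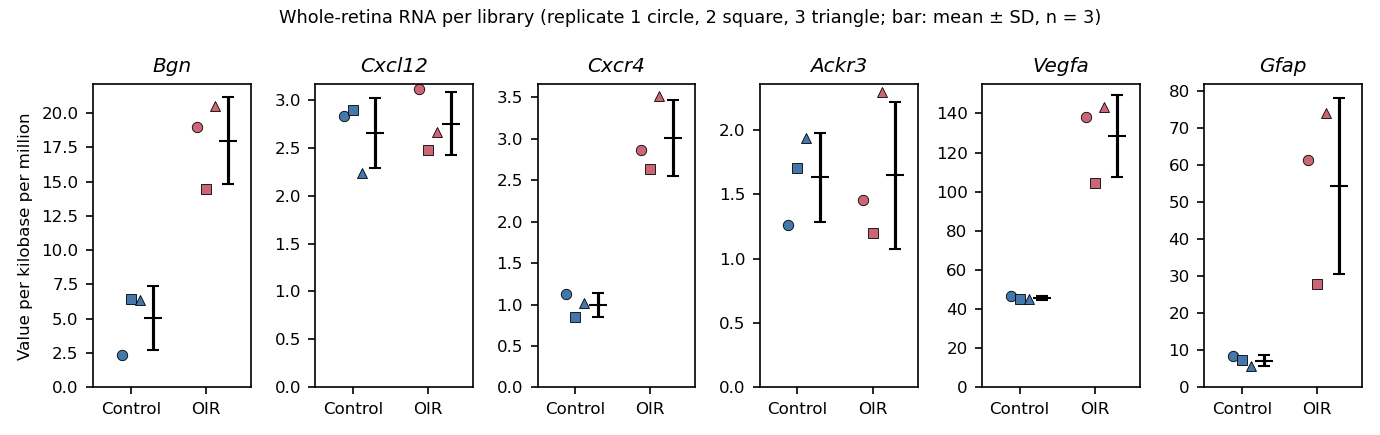
RPKM-type values of 6 genes in each library, with replicate 1 as a circle, 2 as a square and 3 as a triangle, and the mean with its SD beside them (n = 3). Bgn, Cxcr4, Vegfa and Gfap were higher in each OIR library than in any Control library, while the groups overlapped for Cxcl12 and Ackr3.

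Over the retina as a whole, the genes that rose most in OIR included genes of hypoxia, vessel growth and glial reaction. Ndufa4l2, a mitochondrial gene induced by hypoxia and found in pericytes, rose from 4.01 ± 0.348 to 85.8 ± 18.4 RPKM. Apln, which encodes the vessel growth peptide apelin, rose from 1.82 ± 0.0298 to 25.9 ± 7.91 RPKM, and Adm, the gene of adrenomedullin, rose from 0.333 ± 0.0273 to 9.91 ± 3.92 RPKM. Lyz2, a lysozyme of myeloid cells, rose from 2.81 ± 0.554 to 15.6 ± 2.99 RPKM. Among genes that fell were Spc25, from 55.8 ± 6.32 to 21.7 ± 5.19 RPKM, the neuropeptide gene Cck, from 10.9 to 4.29 RPKM (SD 1.67 in OIR), and the GABA receptor gene Gabra4, from 2.96 ± 0.448 to 0.856 ± 0.434 RPKM.

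Of 12112 genes tested with limma, 1407 were higher and 875 lower in OIR, together 18.8% of the genes. At an unadjusted p under 0.05 there were 4122 genes. Higher genes made up 61.7% of the calls, and 49.4% with median-of-ratios scaling, which called 1283 genes higher and 1312 lower. With lens reads removed from the total they made up 50.7%, with 1316 genes higher and 1279 lower. A change of at least 2-fold was found in 115 of the higher and 4 of the lower genes. The groups did not overlap in 38.7% of the tested genes, where chance gives 10%, and in 1401 of the higher and 856 of the lower genes. The 10 named genes that rose most were Ndufa4l2, Edn2, Apln, Adm, Gfap, A2m, Mt2, Bcl3, Tagln2 and Lyz2, with log2 fold changes from 4.09 to 2.11. Among those that fell most were Spc25, Cck, Gabra4, Tacr3, Lgi2, Olfm4, Cartpt, Etnppl and Gsg1l2, from -1.34 to -0.87. The counts moved by over 1.5 times when single libraries were left out, to 658 higher and 265 lower without Control 1, 421 lower without Control 2, 513 and 212 without OIR 1, and 697 and 348 without OIR 3, and 1943 genes were lower without both lens-rich libraries. The calls of Edn2, Gfap, A2m, Mt2, Bcl3, Tagln2 and Cck ended without Control 1, Control 2 or OIR 1, at adjusted p from 0.0572 to 0.168, those of Edn2, Gfap, Mt2 and Bcl3 also without Control 3, at 0.0522 to 0.0667, and those of Edn2 and Gfap without OIR 3, at 0.0879 and 0.0788, while without OIR 1 the log2 fold changes were 3.61, 2.52, 2.27, 2.28, 2.24, 2.05 and -1.09.

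**Figure D3:**
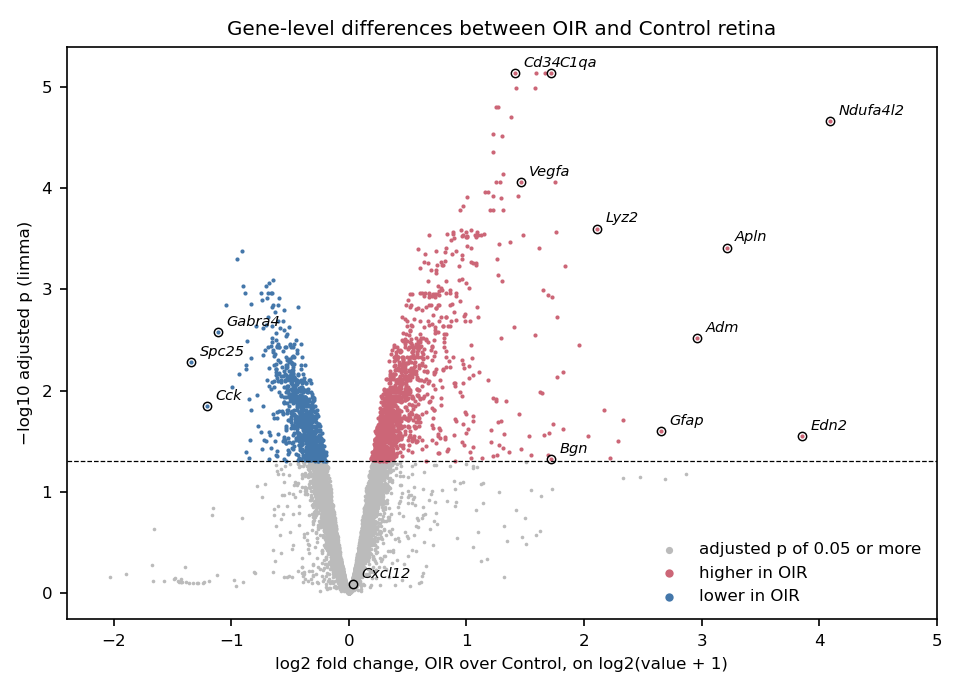
Log2 fold change of each of the 12112 tested genes, OIR over Control, against -log10 of its limma adjusted p, with the dashed line at an adjusted p of 0.05. Red points are the 1407 genes higher in OIR, blue points the 875 lower, and circles mark named genes.

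Most endothelial, tip-cell and pericyte markers were higher in OIR. Of 17 tested endothelial markers, 14 were higher and 1 was lower in OIR, and 15 and 1 adjusted over the list alone (camera adjusted p 1.49e-09, and adjusted p 0.233 with an estimated correlation). The surface protein gene Cd34 rose from 3.77 ± 0.310 to 11.7 ± 0.573 RPKM, Cdh5, the gene of the endothelial junction protein VE-cadherin, from 2.10 ± 0.0695 to 6.51 ± 0.527 RPKM, and Vwf, the gene of von Willebrand factor, from 1.17 ± 0.112 to 4.17 ± 0.0258 RPKM. The lower member was the transporter gene Slco1c1, named after its values were seen, at 2.21 RPKM in Control and 0.853 RPKM in OIR. Of 16 tip-cell and angiogenic genes, 13 were higher, and 16 adjusted over the list alone (camera adjusted p 1.24e-11, and adjusted p 0.293 with an estimated correlation), among them the guidance receptor gene Unc5b, from 2.79 ± 0.235 to 6.45 ± 1.19 RPKM. Of 14 pericyte and smooth muscle markers, 10 were higher by either count (camera adjusted p 2.24e-08, and adjusted p 0.293 with an estimated correlation). Rgs5, a pericyte marker, rose from 17.2 ± 1.38 to 41.0 ± 6.22 RPKM, Pdgfrb, the gene of the pericyte growth factor receptor, from 4.61 ± 0.166 to 7.57 ± 0.574 RPKM, and Notch3 from 0.832 ± 0.0583 to 1.95 ± 0.256 RPKM. The 4 members not past the threshold, named after their values were seen, were Vtn and the smooth muscle genes Acta2, Tagln and Myh11. In Control 1 Acta2 was at 0.882 RPKM, Tagln at 0.763 and Myh11 at 0.0538, against 6.48, 7.87 and 1.34 RPKM in Control 2. Of 13 barrier and Norrin/Wnt genes, 3 were higher by either count, the tight-junction gene Cldn5, the co-receptor gene Lrp5 and the glucose transporter gene Slc2a1, and the list did not pass (camera adjusted p 0.0781, and adjusted p 0.293 with an estimated correlation). It passed without OIR 1, at 0.0365, and the call of Slc2a1 ended without Control 1 or OIR 1, at 0.0502 and 0.0540.

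Genes of red blood cells were also higher. All 4 tested haemoglobin genes were higher by either count, with ratios of the group means from 2.30 for Hbb-bs to 2.75 for Hba-a2 (camera adjusted p 0.000747, and adjusted p 0.293 with an estimated correlation). Each of these 4 calls ended without OIR 1, at adjusted p from 0.0649 to 0.172, and those of Hba-a1, Hbb-bs and Hbb-bt also without Control 1 or Control 2, at 0.0860 to 0.153. Without Control 3 the calls of Hbb-bs and Hbb-bt ended, at 0.0811 and 0.0765, and without OIR 3 those of Hba-a1 and Hbb-bs, at 0.0707 and 0.106.

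Of 24 tested hypoxia-inducible genes, 15 were higher, 9 did not pass and none was lower, and 21 were higher adjusted over the list alone (camera adjusted p 2.17e-09, and adjusted p 0.293 with an estimated correlation). Hilpda, a lipid droplet gene, rose from 9.43 ± 0.849 to 13.4 ± 1.01 RPKM and the stress gene Ddit4 from 82.1 ± 8.49 to 121.9 ± 15.7 RPKM, beside Vegfa and Adm. Of 24 matrix and basement membrane genes, Bgn included, 13 were higher, and 15 adjusted over the list alone (camera adjusted p 2.24e-08, and adjusted p 0.293 with an estimated correlation). The laminin gene Lama4 rose from 1.24 ± 0.205 to 4.23 ± 0.553 RPKM, the crosslinking enzyme gene Loxl2 from 2.01 ± 0.299 to 6.49 ± 1.52 RPKM and the collagen gene Col6a1 from 8.53 ± 1.45 to 15.4 ± 0.732 RPKM. Col4a1, named after its values were seen, was at 8.94 and 8.82 RPKM in Control 1 and Control 2 and at 49.5 RPKM in Control 3, the library with 6.86% lens reads, and did not pass. Bgn and 7 connective tissue genes of this list, named after their values were seen, Dcn, Lum, Fmod, Ogn, Col1a1, Col1a2 and Col3a1, were lower in Control 1 than in both other Controls, while others such as Fn1 were not. Of 14 TGF-beta pathway genes, 7 were higher and 1 lower, and 8 and 1 adjusted over the list alone (camera adjusted p 0.000259, and adjusted p 0.293 with an estimated correlation). Tgfbi rose from 0.480 ± 0.181 to 2.67 ± 0.128 RPKM, and the receptor gene Tgfbr2 from 1.39 ± 0.0344 to 3.15 ± 0.397 RPKM.

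Glial genes moved in both directions. Of 16 reactive gliosis genes, 8 were higher and none lower, and 12 were higher adjusted over the list alone (camera adjusted p 2.17e-09, and adjusted p 0.293 with an estimated correlation). Gfap, the intermediate filament gene of reactive glia, was at 7.25 ± 1.49 RPKM in Control and 54.5 ± 23.8 RPKM in OIR, with 28.0 RPKM in OIR 2 against 61.3 and 74.1 RPKM in OIR 1 and OIR 3. The growth factor gene Fgf2 rose from 0.699 ± 0.235 to 5.17 ± 1.79 RPKM, and Nes, the gene of nestin, from 1.40 ± 0.0977 to 5.49 ± 1.62 RPKM. Of 13 markers of Müller glia, the main glial cell of the retina, 6 were lower and 3 higher by either count (camera adjusted p 0.0445, and adjusted p 0.379 with an estimated correlation). The water channel gene Aqp4 fell from 20.8 ± 1.04 to 13.6 ± 1.74 RPKM and the transporter gene Abca8a from 35.1 ± 3.96 to 23.0 ± 3.13 RPKM, while the transcription factor gene Sox9 rose from 5.43 ± 0.710 to 9.26 ± 1.59 RPKM. The Müller list did not pass with median-of-ratios scaling, at an adjusted p of 0.0843, and did not pass without Control 1, Control 3 or OIR 1, at 0.0552, 0.0533 and 0.0502. It also did not pass with the lens covariate, without both lens-rich libraries or with lens reads removed, at 0.0629, 0.0536 and 0.0797. Of 7 astrocyte markers, 2 were higher, Gfap and Pdgfra, and 4 adjusted over the list alone (camera adjusted p 0.0320, and adjusted p 0.293 with an estimated correlation), and this list did not pass without Control 1 or Control 2, at 0.0520 and 0.0529.

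Most markers of microglia and macrophages were higher in OIR. Of 16 tested markers, 14 were higher by either count and none was lower (camera adjusted p 2.2e-13, and adjusted p 0.293 with an estimated correlation). C1qa, which encodes a chain of the complement protein C1q, rose from 5.55 ± 0.171 to 20.7 ± 2.69 RPKM, the adaptor gene Tyrobp from 3.00 ± 0.371 to 9.67 ± 0.404 RPKM, and Laptm5 from 2.68 ± 0.215 to 8.10 ± 0.931 RPKM. Of 10 complement genes, 4 were higher by either count (camera adjusted p 0.000187, and adjusted p 0.293 with an estimated correlation), C1qa, C1qb, C1qc and C4b, and the first 3 of these are also on the microglia list. The call of C4b ended without OIR 1, Control 1 or Control 2, at adjusted p of 0.126, 0.104 and 0.0989. Of 14 interferon and antigen-presentation genes, 7 were higher, and 9 higher and 1 lower adjusted over the list alone (camera adjusted p 4.8e-05, and adjusted p 0.293 with an estimated correlation). The class I genes H2-D1 and H2-K1 rose from 26.1 ± 1.13 to 55.1 ± 9.47 RPKM and from 9.15 ± 0.473 to 20.5 ± 5.35 RPKM, and Irf7 rose from 5.57 ± 1.22 to 13.9 ± 2.65 RPKM. Only 4 of 20 chemokine and inflammation genes could be tested and none passed by either count (camera adjusted p 0.512, and adjusted p 0.652 with an estimated correlation), but with no filter the 20 genes passed as higher, at 0.00750. Nfkbia was at 8.90 ± 1.22 RPKM in Control and 11.0 ± 1.61 RPKM in OIR. No blood leukocyte marker of 14 reached the minimum for testing.

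Among markers of inner retinal neurons, more were lower than higher in OIR, and many did not pass. Of 19 amacrine cell markers, 14 were lower and 1 higher, and 15 and 1 adjusted over the list alone (camera adjusted p 3.38e-08, and adjusted p 0.293 with an estimated correlation). Th, the gene of the dopamine synthesis enzyme tyrosine hydroxylase, fell by 0.68 on the log2 scale, from 3.15 ± 0.162 RPKM in Control, and Gad1, the gene of a GABA synthesis enzyme, from 84.6 ± 6.12 to 53.7 ± 10.31 RPKM. Of 15 ganglion cell markers, 7 were lower, and 12 adjusted over the list alone (camera adjusted p 3.63e-07, and adjusted p 0.293 with an estimated correlation). Nefh, a neurofilament gene, fell from 55.0 ± 3.59 to 34.9 ± 5.46 RPKM. Of 18 bipolar cell markers, 7 were lower, and 9 adjusted over the list alone (camera adjusted p 1.94e-05, and adjusted p 0.323 with an estimated correlation), among them the glutamate receptor gene Grik1, from 25.1 ± 2.92 to 16.2 ± 1.63 RPKM. Of 5 horizontal cell markers, Calb1 was lower, and 3 were lower adjusted over the list alone (camera adjusted p 0.0140, and adjusted p 0.293 with an estimated correlation). Of 16 presynaptic genes, 4 were lower and 1 higher, and 6 and 1 adjusted over the list alone (camera adjusted p 0.0445, and adjusted p 0.580 with an estimated correlation). Snap25 fell from 554.0 ± 43.3 to 397.3 ± 32.6 RPKM, and the photoreceptor calcium channel gene Cacna1f rose from 47.6 ± 1.28 to 62.6 ± 3.28 RPKM. The presynaptic list did not pass with median-of-ratios scaling, at an adjusted p of 0.0634, nor with lens reads removed, at 0.0591, nor without Control 1, Control 2 or OIR 3, at 0.0761, 0.116 and 0.0643.

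Of 18 rod genes, 4 were higher by either count, with a list median log2 fold change of 0.10, which was 0.03 without Control 3 and 0.15 without Control 2 (camera adjusted p 0.0395, and adjusted p 0.580 with an estimated correlation). Nrl, the rod transcription factor gene, was at 567.7 ± 26.1 RPKM in Control and 663.3 ± 11.99 RPKM in OIR, and Samd7, a gene of photoreceptor nuclei, at 50.6 ± 3.92 and 77.4 ± 14.2 RPKM. The call of Samd7 ended without each library other than OIR 2, at 0.0563 to 0.0721. The call of Nrl ended with median-of-ratios scaling, at 0.0588, and without each library other than Control 3, at 0.0575 to 0.176. The rod list did not pass with no filter or the filter of 1 CPM, at 0.0681 and 0.0510, without both lens-rich libraries, at 0.109 with a median of 0.04, or without Control 3, OIR 1 or OIR 2, at adjusted p of 0.108, 0.0598 and 0.0595. Of 12 cone genes, 2 were higher and 1 lower, and 5 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p 0.155, and adjusted p 0.580 with an estimated correlation). The short-wavelength opsin gene Opn1sw rose from 134.4 ± 5.60 to 195.6 ± 11.7 RPKM, and the cone transducin gene Gnb3 from 190.1 ± 6.15 to 309.4 ± 57.1 RPKM.

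Of 16 cholesterol synthesis genes, 8 were lower and none higher, and 11 were lower adjusted over the list alone (camera adjusted p 1.53e-06, and adjusted p 0.293 with an estimated correlation), with Fdps at 34.0 ± 0.420 RPKM in Control and 24.7 ± 4.52 RPKM in OIR. Its call ended without OIR 1, at an adjusted p of 0.0642 and a log2 fold change of -0.35, and without each other library except OIR 2, at 0.0599 to 0.0627. Of 13 stress and p53 genes, 5 were higher, and 7 adjusted over the list alone (camera adjusted p 0.00314, and adjusted p 0.293 with an estimated correlation), including the cell-cycle inhibitor gene Cdkn1a, from 3.02 ± 0.147 to 8.96 ± 1.70 RPKM. Of 8 immediate early genes, 5 were higher, and 7 adjusted over the list alone (camera adjusted p 0.000310, and adjusted p 0.293 with an estimated correlation), including Fos, from 10.6 ± 1.61 to 21.8 ± 4.16 RPKM. Of 7 pigment epithelium genes, 1 was lower by either count, Rgr, from 6.45 ± 1.05 to 3.61 ± 0.649 RPKM (camera adjusted p 0.00168, and adjusted p 0.293 with an estimated correlation), and this list did not pass without both lens-rich libraries, at an adjusted p of 0.0536. Among 5 testable cell-cycle genes, Mcm2 was higher by either count, and the list did not pass (camera adjusted p 0.155, and adjusted p 0.542 with an estimated correlation). The call of Mcm2 ended without Control 1, Control 3, OIR 1 or OIR 3, at 0.0882, 0.0566, 0.112 and 0.0824. With no filter the 20 cell-cycle genes passed as higher, at an adjusted p of 3.86e-05, as did 16 of them with the filter of 1 CPM, at 0.000333. Of 12 clock genes, 2 were higher and 1 lower, and 2 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p 0.503, and adjusted p 0.802 with an estimated correlation), with a median log2 fold change of -0.04 where fry gave the opposite sign. This median was 0.01 without Control 1, 0.02 without Control 2 and -0.09 without Control 3. None of 20 tested lens genes passed by either count, and the list did not pass (camera adjusted p 0.0526, and adjusted p 0.667 with an estimated correlation), but it passed as lower with no filter, at 0.0387, and without Control 1, Control 2 or OIR 2, at 5.75e-05, 0.00310 and 0.00270. Its median log2 fold change was -1.40 with all libraries and turned to 1.10 without Control 3, where it did not pass, at 0.0990. Both tested corneal epithelial genes were not past the threshold, with Sfn at 1.56 ± 0.396 RPKM in Control and 1.21 ± 0.135 RPKM in OIR. Mitochondrially encoded mRNAs were not analysed here.

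**Figure D4:**
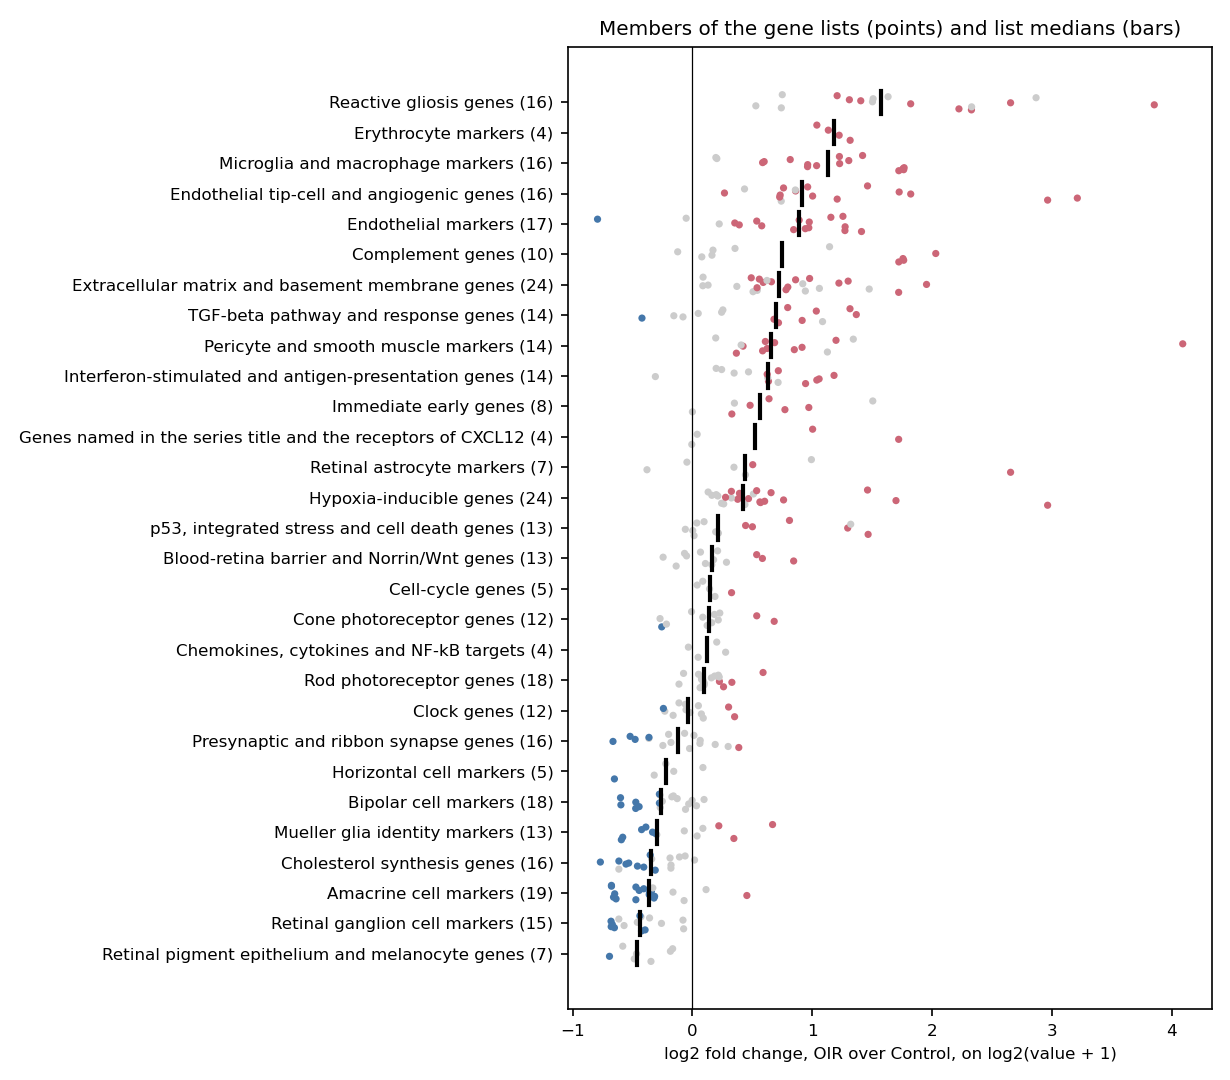
Log2 fold change, OIR over Control, of the tested members of 29 gene lists, with red points higher and blue points lower at a limma adjusted p under 0.05, grey points not past it, and the black bar at the list median. The number of tested members stands in parentheses, and the lens list is left out since its scale is set by Control 3.

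Of the 30 lists tested with camera, 15 were higher, 8 were lower and 7 did not pass. Some lists share genes, so they are not separate evidence. Vegfa and Adm are on the tip-cell and hypoxia lists, and Gfap is on the reactive gliosis and astrocyte lists. The barrier list shares Cldn5 with the endothelial list and Slc2a1 with the hypoxia list. Both scaling alternatives left the directions of the lists in place, and ended the calls of the Müller and presynaptic lists. No list passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry passed 17 lists. These were 14 of the 15 lists called higher, without the rod list, 1 of the 8 called lower, the amacrine list, and 2 that camera did not pass, the list of the study's genes and the barrier list.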

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

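The alternatives that add limma-voom, the lens covariate, the loss of both lens-rich libraries and the removal of lens reads were chosen after seeing the data. No gene called in OIR against Control changed sign in any setting. The count of higher genes stayed within 1.5 times of 1407 under each setting except the 2-fold threshold, at 115, and 3 of the fits with 1 library left out. The count of lower genes was 1356 with upper-quartile scaling, 529 with no filter, 1943 without both lens-rich libraries and 4 at the 2-fold threshold, against 875. With no filter more genes were tested, 17953. With lens reads removed, which changes only the scaling, 1316 genes were higher and 1279 lower, against 1233 and 1356 with upper-quartile scaling. The upper-quartile factor was lowest in Control 3, at 0.947, and highest in OIR 1, at 1.02. A correction for lens reads alone thus moved the count of lower genes nearly as far as upper-quartile scaling. For the other settings the cause was not tested. With 1 library left out, higher genes ranged from 513 without OIR 1 to 1754 without OIR 2, and lower genes from 212 without OIR 1 to 1293 without OIR 2. Without Control 1 they were 658 and 265, without Control 2 941 and 421, and without OIR 3 697 and 348, with fewer samples in each fit.

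Bgn kept its direction in all 16 alternatives, at log2 fold changes from 1.34 to 2.05 and adjusted p from 0.00129 to 0.176. It lost its call with a pseudocount of 0.1 (1.92, adjusted p 0.0604), with the lens covariate (1.79, 0.0576) and without both lens-rich libraries (2.05, 0.102). With 1 library left out it ranged from 1.34 without Control 1 to 1.91 without Control 2, and the call ended without Control 2, OIR 1, OIR 2 or OIR 3. In a further fit chosen after seeing the data, with a pseudocount of 0.1 and Control 1 left out, the log2 fold change of Bgn was 1.46. Its standard error was 0.140 and its limma adjusted p 0.000883. The low value of Control 1, which stayed in each fit where the call ended with 1 library left out, thus set much of the spread of Bgn. Cxcl12 passed in none of its 16 alternatives, with log2 fold changes from -0.05 to 0.09. Of 106 named genes past the threshold, 72 kept the call whichever library was left out. With an estimated correlation 0 lists were higher and 0 lower, and otherwise 14 to 16 were higher and 6 to 9 lower.

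The replicate numbers were also fitted as a replicate block. Libraries of the same number deviated from their group means with correlations of 0.22, -0.44 and -0.41. These correlations were taken over all tested genes, lens genes included, and that of the lens-rich Control 3 and OIR 2 was 0.49. They thus cannot decide whether libraries of the same number share more than the number. The block gave 1222 higher and 809 lower genes, and ended the call of Bgn, at 1.72 with an adjusted p of 0.132, and of 13 other named genes. The lens list passed as lower with the block, at 0.0446.

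The planned DESeq2 and edgeR alternatives were not run, since the values are not counts. At this depth and spread the simulated test recovered 47.8% of 1.5-fold changes, so smaller changes can go undetected. Far fewer genes were changed in the simulation than were called in the data. The adjusted threshold depends on that share, so recovery in the data can differ. Genes below 1 RPKM in most libraries, such as most chemokines and cell-cycle genes, were not tested.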

Other observations

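All tests in this part except that of the other splits of the libraries were chosen after the result was seen, and those of OIR 2 and of Bgn were also revised after a first form had been run, after which an admixture of unaffected retina in OIR 2, first argued against, and the tissue content of Control 1, first favoured, are left open. The genes in the next paragraph were chosen after their values were seen, and the alternative settings were not applied to them.

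Further vessel, myeloid and hypoxia genes differed in OIR by limma. Cd93, a receptor of endothelial cells, rose from 1.84 ± 0.118 to 8.05 ± 0.853 RPKM (log2 fold change 1.67, adjusted p 7.34e-06), and Plxnd1, the gene of a semaphorin receptor of vessels, from 2.49 ± 0.561 to 8.73 ± 1.41 RPKM (1.48, 0.000294). Mpeg1, a macrophage gene, rose from 1.43 ± 0.0955 to 6.32 ± 0.803 RPKM (1.59, 1.04e-05), and the class II gene H2-Ab1 from 1.32 ± 0.0481 to 7.12 ± 2.23 RPKM (1.77, 0.00190). Epo, the gene of the oxygen-regulated hormone erythropoietin, rose from 0.0900 ± 0.0810 to 1.74 ± 0.764 RPKM (1.30, 0.00301). The cartilage collagen gene Col2a1 rose from 10.9 ± 0.869 to 28.1 ± 3.96 RPKM (1.29, 8.73e-05). Nap1l5 fell from 148.3 ± 12.4 to 88.0 ± 11.2 RPKM (-0.75, 0.00109), and Omg, a myelin-associated glycoprotein gene, from 13.4 ± 0.101 to 7.23 ± 1.78 RPKM (-0.83, 0.00481). All 8 had groups that did not overlap, as had 1401 of the 1407 higher and 856 of the 875 lower genes, so this adds no support.

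The real split of the 6 libraries gave 2282 genes past the threshold, and the highest of the other splits gave 2. As many genes came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

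Lens genes were high in Control 3 and, less so, in OIR 2, where the crystallin gene Cryaa was at 20337 and 1709 RPKM against 45.5 to 196.8 RPKM elsewhere. No biological explanation was tested, and the highest share was in a Control library. Lens tissue carried over at dissection may be the source. The 7 lens fibre genes outside the crystallin family rose by a median of 7.80 on the log2 scale in Control 3 and 4.48 in OIR 2, and the 15 crystallins by 7.63 and 4.44. None of the 22 genes is on another list, and 15 had at least 1 RPKM in each library, so low crystallin expression by the retina itself stays open.

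Genes higher in OIR lay nearer to Control in OIR 2 than in the other OIR libraries. The 1754 genes called higher without OIR 2 reached there a median share of 0.538 of the rise in OIR 1 and OIR 3, where the same share was 1.08 in OIR 1 for 513 genes and 1.28 in OIR 3 for 697 genes. In OIR 2 the list medians were 0.277 for reactive gliosis, 0.329 for haemoglobin, 0.351 for hypoxia, 0.547 for tip-cell, 0.626 for microglia and 0.895 for endothelial genes. Reads taken by lens RNA, 0.592% in OIR 2, are argued against, since they would lower all values by a like small share and the upper quartile of the shares was 0.706. RNA of unaffected retina mixed in may be a source and stays open. The medians of the 10 lists that all 3 libraries give, without reactive gliosis and haemoglobin, had an SD of 0.147 in OIR 2, 0.142 in OIR 1 and 0.299 in OIR 3. Those of all 17 lists of OIR 2 and 13 of OIR 3 had an SD of 0.181 and 0.323. These SDs cannot decide it, since the shares of OIR 1 and OIR 3 were taken against means that include OIR 2. The SDs were also not scaled to the size of the median shares. A difference in stage or severity within OIR, which the design does not name, was not tested.

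Bgn was low in Control 1, and less smooth muscle or connective tissue in that library may be a source. The 4 smooth muscle genes Acta2, Tagln, Myh11 and Cnn1 were all lower there than in both other Controls, with a median difference of -3.18 on log2(value + 0.1), as were 16 of the 26 other genes of the matrix list, with a median over the 26 of -0.802, against 0.18 for 6 pericyte genes. Matrix genes such as Fn1, at 9.25 RPKM in Control 1 against 9.02 and 8.62 RPKM, were not lower, so this source stays open. Against Control 2 and Control 3 alone, these 30 genes differed in OIR by a median of 0.657 with an upper quartile of 0.87. Bgn differed by 1.46 with a 95% interval from 1.14 to 1.78. Of the 30 genes 4 reached that interval or lay above it, with Fn1 the highest at 2.08. These values cannot decide whether the same content is the whole source of the higher Bgn in OIR. The lens-rich Control 3 stood above Control 2 for some of the genes, which lowers their difference. Col4a1 was at 49.5 RPKM in Control 3 against 8.82 in Control 2, and Nid1 at 18.2 against 1.83, while others such as Col1a1 were not higher.

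Y-linked genes also differed between libraries. Ddx3y was at 9.41 RPKM in Control 3, 5.63 in OIR 1 and 4.84 in OIR 2, and at most 0.0777 RPKM in Control 1, Control 2 and OIR 3. The libraries of each group thus did not all come from the same animal. Y-linked RNA was spread unevenly over the groups, and no fit held a term for it.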
